A study of Mus musculus with 2 samples.

How the data were processed

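Polyadenylated RNA was profiled in 2 libraries of mouse midbrain at 12.5 days of gestation, replicate 1 from 120 pooled embryos and replicate 2 from 88. Per the labels, libraries were primed with oligo-dT from 10 ng of RNA, fragmented by tagmentation and spiked with ERCC control RNAs. Replicate numbers and pool sizes were taken from the labels, and both libraries belong to the only group.

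For each library, the authors deposited 4 tables, a gene table and a transcript table against each of 2 annotations (M4 and M21) of assembly mm10, per the manifests that accompany the tables. Per the file headers, each row holds an expected count, which is an estimated number of reads that need not be whole and is not scaled. The deposited TPM is scaled to the same total in each library over all rows, spike-ins included. The deposited FPKM is scaled by effective length and by the number of fragments. The transcript tables also hold, per the file headers, the percent of a gene's TPM taken by each transcript. The aligner and the quantification tool and version were not given in the sources used here; the column names are those of RSEM. The strand setting used in counting was likewise not given in the sources used here. Gene symbols, biotypes, coordinates and coding lengths came from the GENCODE M21 annotation, which matched all 55536 gene identifiers of the M21 tables and 42462 of 43346 of the M4 tables without their version. Pseudogenes and other near-identical copies share reads that such estimates divide by a model.

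M21 was the main quantification, as the newer annotation. Rows that name no gene were kept out of library sizes and ratios. They took 4.02% of the counts in replicate 1 and 3.38% in replicate 2, almost all of it ERCC; 26248 rows with numeric identifiers held 18 and 29 counts and phiX held 0. Total expected counts were 30274342 and 38421860. Deposited TPM was used as given for levels, with 1 TPM in both libraries as the limit of detection. List medians were compared on log2(TPM + 0.1), which understates differences between low values. A list's median level was placed among 10000 random lists of protein-coding genes of the same size.

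Ratios between the libraries used expected counts rounded to whole numbers and TMM scaling (edgeR 4.0.16 in R 4.3.3). Each log2 ratio carries an exact conditional binomial (Clopper-Pearson) 95% interval, and genes needed at least 10 counts in a library. A gene was counted as different at a 2-fold ratio with an interval excluding equality. The median ratio of each list was placed among 10000 random lists of the same size drawn from 50 bins of mean expression. With 1 library per pool no test across pools was possible. Dispersion came from edgeR with an intercept-only design. A count of 0 was treated as up to 3 counts when a fold was bounded, and such a bound can lie beyond the limit of the 95% interval. Trends with GC content and gene length were fitted with natural splines over 19767 of 19776 genes and explained 2.11% of the variance.

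The 36 gene lists, the 26 genes of the transcript comparison, the limits, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names list members (the highest, the lowest and the exceptions to a list's majority), the 20 highest nuclear coding genes, the 10 largest ratios in each direction at 5 TPM or more, and the 10 largest differences between annotations, with mitochondrial and histone genes as groups. Pax6, a list member, and some other list members with large ratios are also named. All 322 list genes were found in the annotation. Further lists of rostral, ventral midbrain and mesenchymal genes, and of 4 X-linked genes known to escape inactivation, were written after the values of the fixed lists had been seen and prompted them, but before the values of their own members were looked at. Foxd1, already a member of a fixed list, was taken out of the rostral one. Their results stand in the closing section.

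The ratio procedure was tested on simulated data, with Poisson counts for 55536 genes at the real depths. At a 1.5-fold limit it recovered 97.1% of genes changed 2-fold, 98.5% of those changed 3-fold and 100% of those changed 4-fold. Recovery at the 2-fold limit used for the real libraries was not computed. For genes changed 2-fold it would be lower, since their median absolute log2 ratio was 0.997. The intervals covered 95.2% of unchanged genes, and at the 2-fold limit 143 of 19582 unchanged genes were counted as different. The procedure for list levels was tested on lists drawn from 22028 protein-coding genes, and 4% of 200 unchanged lists fell outside the central 95%. Those lists came from the same genes as the random lists, so a share near that was fixed in advance. Raised lists, drawn from genes at 1 TPM or more with the median multiplied by 4, were found in 95.5% of cases. The annotation procedure was checked only on TPM values multiplied without noise. The procedure for list shifts was tried only on a shifted list (percentile 100) and an unshifted list (percentile 40.95). Alternatives were another limit of detection (0.5 or 5 TPM), FPKM, TPM rescaled over nuclear coding genes, the M4 tables, each replicate alone, pseudocounts of 1 and 0.01, detected members only, DESeq2 1.42.0 size factors, total counts, spike-in totals, no count minimum or 50, a 1.5-fold limit, a share of 80%, and counts scaled to a fixed total for the annotations. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and matplotlib 3.10.9 for the plots.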

Results

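The series measured polyadenylated RNA in the midbrain of mouse embryos at 12.5 days of gestation, a stage at which the region still holds dividing neuroepithelium while many of its neurons have already formed. Both libraries came from the same mouse strain and from pooled male and female embryos. Replicate 1 was made from 120 embryos and replicate 2 from 88. They form a single group of 2 biological replicates, so no contrast between conditions exists, and every comparison is between gene groups within the tissue, between the 2 pools, or between the 2 quantifications deposited for each library. Total expected counts were 30274342 in replicate 1 and 38421860 in replicate 2, of which 29056772 and 37122519 belonged to annotated genes. Levels are given as TPM (transcript abundance scaled to a fixed total per library), mean ± SD with n = 2, and coordinates are those of mouse assembly mm10.

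The most abundant nuclear protein-coding transcripts included those of cytoskeletal proteins and globins. Actb, which encodes cytoplasmic beta-actin, stood at 10302 ± 659 TPM (ENSMUSG00000029580.14, chromosome 5, 142903115 to 142906754, minus strand), and Tuba1a, a tubulin of young neurons, at 7367 ± 272. Hbb-y, an embryonic beta-like globin, reached 6764 ± 598, and the adult-type alpha globin Hba-a2 reached 5196 ± 722. The actin-binding thymosin Tmsb4x stood at 4802 ± 73.5, the ferritin light chain Ftl1 at 4565 ± 282 and the microtubule regulator Stmn1 at 3859 ± 5.32. The rest of the 20 highest were Hist1h2ap, Tmsb10, Ppia, Nnat, Ubb, H3f3a, Eef1a1, Actg1, Cfl1, Hba-a1, Hmgn2, Hspa8 and Ptma, the last at 2108 ± 69.3. Hba-a1 and Hba-a2 are near-identical copies, so the split of reads between them is uncertain. Among all genes, Rn7s1 and Rn7s2, copies of the signal recognition particle RNA with identical values, stood at 8142 ± 173 each, the ribosomal RNA gene CT010467.1 at 6855 ± 1023 and the nuclear noncoding RNA Malat1 at 6218 ± 59.7. The pseudogene Gm28437, which resembles mitochondrial sequence, stood at 4668 ± 240, and its reads cannot be separated from those of its source with certainty. The 10 highest genes took 7.58% ± 0.181 of the TPM of all annotated genes, spike-ins left out, and the 100 highest 24.1% ± 0.329.

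In all, 15600 of 55536 annotated genes had at least 1 TPM in both libraries, 13083 of them among the 22028 protein-coding genes. The median level of those coding genes was 22.2 TPM. Protein-coding genes took 95.1% ± 0.198 of gene counts, mitochondrial genes 1.07% ± 0.152 and genes annotated as ribosomal RNA 1.05% ± 0.161. Within the mitochondrial group mt-Atp6, a subunit of ATP synthase, was highest at 5128 ± 332 TPM. Genes named as replication-dependent histones took 0.197% ± 0.00772 of gene counts, and 55 of the 71 were detected. Hist1h2ap, at 3844 ± 222 TPM, made up most of their summed 5262 TPM in replicate 1 and 5626 in replicate 2. The symbol rule for that group also took H1f0, a linker histone made outside S phase, at 434 ± 23.2. For a gene of median length, the level that a count of 0 still allows was 0.0792 TPM in replicate 1 and 0.0625 in replicate 2.

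Midbrain identity genes were present over a wide range of levels. Otx2, a homeobox gene of the forebrain and midbrain, stood at 143 ± 2.58 TPM (ENSMUSG00000021848.16, chromosome 14, 48657677 to 48673819, minus strand), and Cnpy1, a gene of the isthmus linked to Fgf signalling, at 94.8 ± 29.6. En1 and En2, the engrailed genes of the midbrain and hindbrain border, were lower, at 6.83 ± 1.74 and 1.39 ± 0.354. In the list of midbrain and isthmus genes 11 of 12 were detected, with a median of 5.74 TPM, and Pax2 was the exception at 0.25 in both libraries. All 7 dorsal midbrain genes were detected with a median of 32.2 TPM. They ran from Pax7 at 3.91 ± 0.764 to Tfap2b, a transcription factor, at 74.9 ± 5.02.

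Genes used as markers of neighbouring regions were also found. The telencephalic list had 9 of 11 members detected and a median of 13.8 TPM. Lhx2, a LIM homeobox gene, led at 93.8 ± 10.7. Eomes (1.44 ± 1.09) was under 1 TPM in replicate 2. The diencephalic and hypothalamic list had 8 of 9 detected with a median of 5.58, led by the Wnt effector Tcf7l2 at 345 ± 108, and Six6 lay at 0.055 ± 0.0636. Lhx2, Dlx1 and Tcf7l2 are not restricted to the regions whose lists they belong to. The list of 17 Hox and hindbrain segmentation genes had a median of 0.03 TPM, and Hoxa4, Hoxb4, Hoxc6, Hoxb8 and Hoxc8 had no counts in either library. The cerebellar list had 3 of 5 detected, from Ptf1a at 0.86 ± 0.735 to Barhl1 at 30.9 ± 7.57. Atoh1, a determinant of cerebellar granule neurons, was detected in replicate 2 only, at 2.06 TPM against 0.69, as was Ptf1a at 1.38 against 0.34, so that replicate 2 alone had all 5.

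The list medians were compared on the scale of log2(TPM + 0.1). The midbrain list lay below the telencephalic list by -1.25 in replicate 1 and -1.09 in replicate 2, a mean of -1.17 ± 0.11 (SD, n = 2). It lay above the Hox list by 5.71 and 5.29, a mean of 5.50 ± 0.30. The neural progenitor list lay below the list of postmitotic neurons by -1.47 and -1.69, a mean of -1.58 ± 0.16. Each gap was several times the difference between the libraries, and genes are not replicates, so no p-value is attached. The size of the midbrain to Hox gap depends on how values near 0 are treated. When only detected members were kept, the Hox list was nearly empty and the difference was -0.12.

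**Figure D1:**
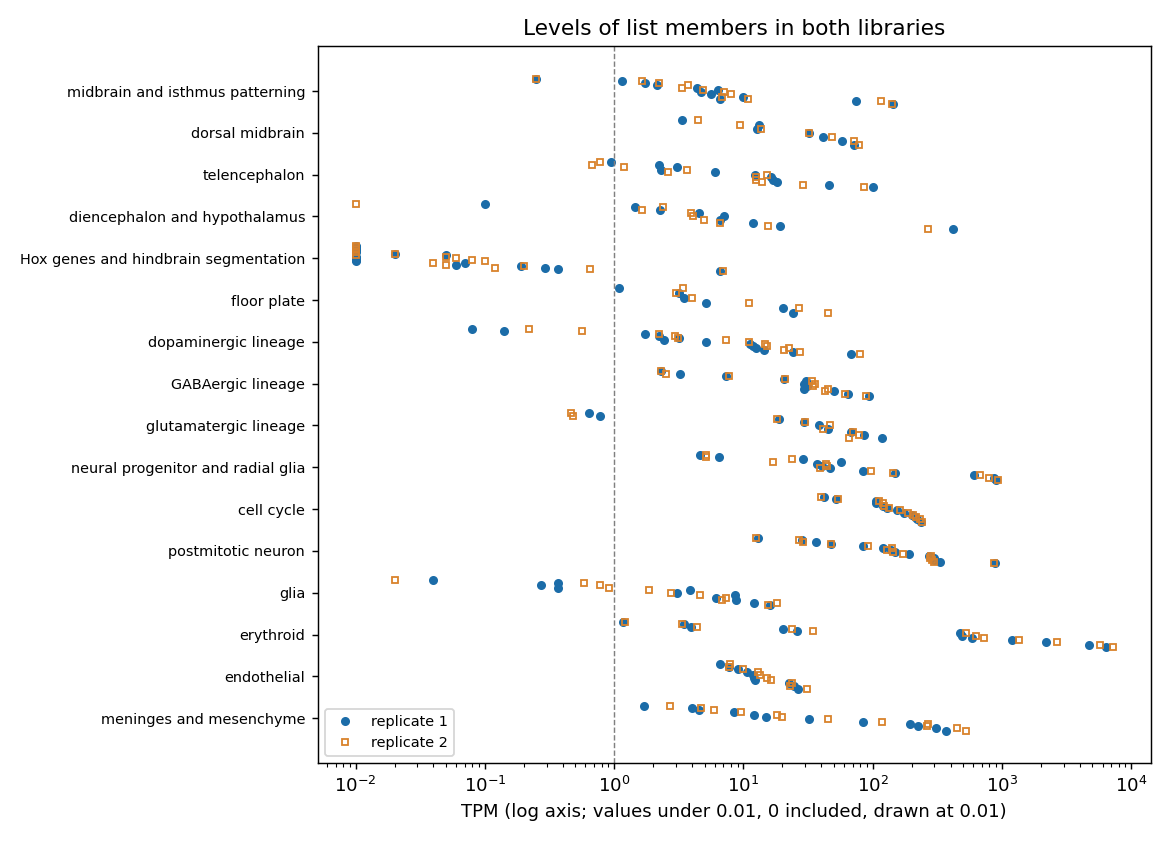
TPM of each list member (log axis, values under 0.01 drawn at 0.01) in replicate 1 (filled circles) and replicate 2 (open squares), for 16 of the lists, with a dashed line at 1 TPM. Most points of the Hox list lie below the line, while all cell cycle and postmitotic neuron genes lie above it.

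Progenitors and neurons were both strongly represented. All 12 genes of the progenitor and radial glia list were detected, with a median of 42.6 TPM, from Sox3 at 4.86 ± 0.325 to Vim, an intermediate filament of radial glia, at 919 ± 21.1. The 12 cell cycle genes had a median of 145, from Mki67 at 40.9 ± 1.43 to the topoisomerase Top2a at 238 ± 0.827. The 14 neuronal genes had a median of 139, from Rbfox3 at 12.8 ± 0.339 to the neuronal tubulin Tubb3 at 872 ± 14.8. Medians of all 3 lists lay at or above percentile 99.5 of random lists of protein-coding genes, which is a description of these libraries. In the glial list 7 of 11 were detected with a median of 2.91; the myelin gene Mbp was highest at 15.8 ± 0.226, and the astrocyte filament gene Gfap stood at 0.03 ± 0.0141.

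Among neuronal lineages, GABAergic and glutamatergic genes stood highest. All 11 GABAergic genes were detected with a median of 32.6 TPM, with Zfpm1 lowest at 2.31 ± 0.0212 and the transcription factor gene Gata3 at 62.5 ± 2.58. Of the 9 glutamatergic genes 7 were detected with a median of 42.8; the proneural gene Neurog2 led at 91.9 ± 37.9, and the vesicular transporters Slc17a7 and Slc17a8 stood at 0.63 ± 0.212 and 0.55 ± 0.127. The dopaminergic list had 11 of 13 detected and a median of 8.04. Its highest member was Msx1 at 73.6 ± 8.54, a gene that also marks the roof plate. Th, which encodes the rate-limiting enzyme of dopamine synthesis, stood at 17.4 ± 7.02, while the dopamine transporter Slc6a3 (0.35 ± 0.297) and Aldh1a1 (0.15 ± 0.0990) fell short of 1 TPM. Oculomotor and cholinergic genes were detected in 3 of 7 cases, with Isl1 at 23.0 ± 9.39 and the acetylcholine-synthesising enzyme Chat at 0.145 ± 0.00707. Of 5 serotonergic genes only Nkx2-2 passed, at 9.08 ± 2.55.

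Signalling genes of the patterning centres were detected throughout. The floor plate list was complete (6 of 6, median 5.88), from Ferd3l at 2.25 ± 1.63 to the matrix protein gene Spon1 at 34.6 ± 14.7. The roof plate list had 6 of 7 (median 8.41), with Gdf7 under the limit at 0.735 ± 0.219. All 8 Shh pathway genes (median 11.8), 9 Notch genes (median 40.4), 8 Wnt genes (median 16.0), 14 Fgf genes (median 8.72) and 16 axon guidance genes (median 43.1) were detected. Hes5, a Notch target, was the highest of these at 647 ± 50.6, and Efna2, a repulsive guidance ligand, was the highest guidance gene at 93.3 ± 9.09.

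Transcripts of blood, vessels and surrounding tissue were part of both libraries. The 12 erythroid genes had a median of 533 TPM, from the transcription factor gene Gata1 to Hbb-y. All 10 endothelial genes (median 13.2), 8 pericyte genes (median 4.58) and 9 of 10 microglial genes (median 5.88) were detected, with Ptprc short of the limit at 0.95 ± 0.0566. The 12 genes of meninges and mesenchyme had a median of 28.0, led by the collagen genes Col3a1 at 450 ± 112 and Col1a1 at 378 ± 96.5. The surface epithelium list had 7 of 8 detected (median 4.65, Trp63 at 0.975 ± 0.417), the choroid plexus list 5 of 5 (median 4.99, Ttr highest at 25.7 ± 17.2) and the sensory ganglion list 5 of 7 (median 2.67, Scn10a without counts). Cartilage genes passed in 3 of 6 cases (median 1.43, Col9a1 highest at 13.3 ± 7.13) and skeletal muscle genes in 2 of 8 (median 0.83, Tnnt1 highest at 8.52 ± 0.255), or in 6 of 8 at a limit of 0.5 TPM. Housekeeping genes had a median of 1355 and hypoxia genes of 26.2, all 8 detected in each, while 7 of 10 immediate early and heat shock genes passed (median 1.75). Within that last list Jun was highest at 58.6 ± 6.41 and Hspa1b lowest at 0.085 ± 0.120, a gene whose reads are shared with its near-identical copy Hspa1a. In 31 of the 36 lists more members were detected than not.

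The 2 pools were then compared gene by gene. Olig3, a transcription factor of dorsal and thalamic progenitors, was higher in replicate 1 by a log2 ratio of 2.55 (1841 counts against 405; ENSMUSG00000045591.6, chromosome 10, 19356533 to 19358604, plus strand). Afp, which encodes alpha-fetoprotein, had 420 counts against 4, a log2 ratio of 7.08 with a counting interval of 5.71 to 8.96. The Wnt agonist gene Rspo3 was higher in replicate 1 by 1.95 and the eye and forebrain gene Pax6 by 1.75, at 57.2 against 16.9 TPM. Matn4, a cartilage matrix protein gene, was higher in replicate 2, with a log2 ratio of -2.22 (102 counts against 611; chromosome 2, 164389393 to 164405160, minus strand).

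Of 19885 genes with at least 10 counts in a library, 841 differed at least 2-fold with a 95% counting interval that excluded equality, 354 higher in replicate 1 and 487 higher in replicate 2. With a minimum of 50 counts 208 of 15158 did, 77 and 131 in the same order, and no simulation was run at that minimum. At the minimum of 10 counts, 143 of 19582 unchanged genes in simulated libraries passed the 2-fold limit by counting error alone. Scaled to spike-in totals instead, the count was 1090, with 217 higher in replicate 1 and 873 in replicate 2, so the share higher in replicate 1 went from 42.1% to 19.9%; that scaling moved the median log2 ratio of all genes to -0.28, so the ratios here are relative to the bulk of genes. Among 11594 genes at a mean of 5 TPM or more, 67 differed 2-fold, 30 higher in replicate 1 and 37 in replicate 2. Across genes, which are not independent replicates, the libraries correlated with Pearson's r of 0.988 and Spearman's rho of 0.992, and the common biological coefficient of variation was 0.0886. The spread between them exceeded sampling noise, with a chi-square of 8.26 per degree of freedom. These are single libraries per pool, so the ratios compare the libraries and carry no p-value. Intervals and detection limits cover counting error only and not variation between pools. Reads lacked molecular identifiers, so amplification duplicates could not be told apart and the intervals may be too narrow.

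Most of the largest ratios at 5 TPM or more belonged to genes whose counts are uncertain. Higher in replicate 1, besides Afp, Olig3 and Rspo3, were mt-Nd4l (239 counts against 0, 102-fold with the 0 set to 3), Rpl30-ps10 (53 against 0, 22.7-fold likewise), Gm14434 (log2 ratio 3.58), Duxbl3 (2.62), Gm20689 (1.98), C130093G08Rik (1.98) and Apoo-ps (1.79). Higher in replicate 2, besides Matn4, were Gm12191 (0 counts against 78, 20.2-fold with the 0 set to 3), Gm9830 (0 against 92, 23.8-fold likewise) and Snora43 (0 against 11, 2.85-fold likewise). So were Gm24029 (-3.22), Gm14567 (-2.96), Gm7367 (-2.75), Zfp969 (-2.68), Gm14539 (-2.34) and Gm25184 (-2.14). Rpl30-ps10, Gm20689, Apoo-ps, Gm12191, Gm9830, Gm14567, Gm7367 and Gm14539 are processed pseudogenes, which share reads with their parent genes. Gm14434 and Zfp969 belong to a cluster of similar zinc-finger genes on chromosome 2. On the mitochondrial genome mt-Nd4l (9877 to 10173) overlaps mt-Nd4 (10167 to 11544) only at its end. That overlap does not account for 239 counts against 0, and the cause was not tested. Snora43, Gm24029 and Gm25184 are genes of small nuclear and nucleolar RNAs, a class that oligo-dT priming is not meant to capture, and the strand used in counting was not given in the sources used here.

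Gene groups moved together between the pools. Forebrain genes were higher in replicate 1: the median log2 ratio of the telencephalic list was 0.45, with 8 of 11 members above equality beyond counting error, among them Emx1 (1.25), Tbr1 (1.39) and Eomes (1.58), T-box and homeobox genes of the cortex. Bcl11b went the other way (-0.23). The diencephalic list shifted by 0.41, with 6 of 8 above and Rax (-0.67) below; Barhl2 stood at 0.88 and Tcf7l2 at 0.68. Most genes of the ventral midbrain lists were higher in replicate 2. The floor plate list had a median of -0.70 with 4 of 6 below, including Foxa2 (-1.05) and Spon1 (-0.87). Its members Shh (-0.19) and Foxa1 (0.12) stayed within counting error. The dopaminergic list, which also holds Foxa2, had a median of -0.42 with 11 of 13 below, including Th (-0.82) and the protease gene Corin (-1.57). The midbrain and isthmus list had a median of -0.38, but its members split, with Cnpy1 (-0.60), Fgf17 (-0.75) and 5 others below equality and Wnt1 (0.58), Fgf8 (0.68), Sp8 (0.34) and Otx2 (0.07) above it. These medians lay beyond the central 95% of 10000 random lists matched on expression, a description of these libraries.

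Connective tissue genes were higher in replicate 2 without exception in their lists. All 12 mesenchymal genes had ratios below equality, 11 beyond counting error, with a median of -0.40 and Col1a1 at -0.49. All 5 cartilage genes compared lay below, with a median of -1.49, or -1.86 with Matn1, absent from replicate 1, placed at its bound. Epithelial (-0.43), ganglion (-0.46), erythroid (-0.17), endothelial (-0.21) and pericyte (-0.21) medians were also lower in replicate 1, as were those of axon guidance (-0.12) and dorsal midbrain (-0.12). Members that went the other way beyond counting error were Epcam (0.50) among epithelial, Isl1 (0.80) among ganglion, Kdr (0.13) among endothelial, Notch3 (0.09) among pericyte and Zic1 (0.56) among dorsal midbrain genes, and 4 of 16 guidance genes, led by Dcc (0.31) and Epha7 (0.26). The oculomotor list (-0.56) was lower although it also holds Isl1. The choroid plexus list was higher in replicate 1 (0.79), led by Clic6 (1.56) and the thyroid hormone carrier gene Ttr (1.51), which is also expressed in yolk sac and liver, whereas Aqp1 lay at -0.68. Smaller positive medians were found for Wnt (0.17), glutamatergic (0.12), Shh (0.11) and postmitotic neuron genes (0.09), and under spike-in scaling these became -0.10, -0.15, -0.16 and -0.18 because the whole distribution moved. Telencephalic (0.18), diencephalic (0.14) and choroid plexus (0.52) medians stayed positive under that scaling, and the roof plate median came to 0.00.

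The sex-linked genes moved in opposite directions. Xist, the noncoding RNA of the inactive X chromosome, was higher in replicate 1 (0.70, 9177 counts against 7243), and the Y-linked genes Kdm5d (-0.78), Uty (-0.69), Ddx3y (-0.61) and Eif2s3y (-0.41) were higher in replicate 2. In total 22 of 36 lists lay beyond the central 95%, 7 toward replicate 1 and 15 toward replicate 2, where genes drawn independently would give 1.8. Members of a list can vary together and some lists share members, so 1.8 is not the number expected between 2 pools. The roof plate list (0.27) had 2 members above and 3 below, and the cerebellar list (-0.34) 2 above and 3 below. With a minimum of 50 counts the roof plate (0.03), glutamatergic (0.02) and cerebellar (0.03) lists no longer stood apart.

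Shh genes lay just within the central 95% of random lists (percentile 97.2) and just past its edge without a count minimum or with a minimum of 50 counts (97.53). Other lists stayed close to the bulk of genes. Medians were 0.01 for GABAergic, 0.05 for progenitor, -0.01 for cell cycle, -0.05 for glial, -0.05 for Notch, -0.04 for Fgf, -0.12 for microglial, -0.10 for muscle, -0.03 for housekeeping, 0.02 for immediate early and -0.01 for hypoxia genes. Serotonergic (-0.31, 4 members) and Hox genes (-0.68, 3 members) lay within the range of random lists, and without a count minimum the Hox median was 0.36 (7 members), so its direction is not established. Within the glial list Olig1 (1.10) and Olig2 (0.92) were higher in replicate 1, while Pdgfra (-0.53), which also marks mesenchyme, was higher in replicate 2.

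**Figure D2:**
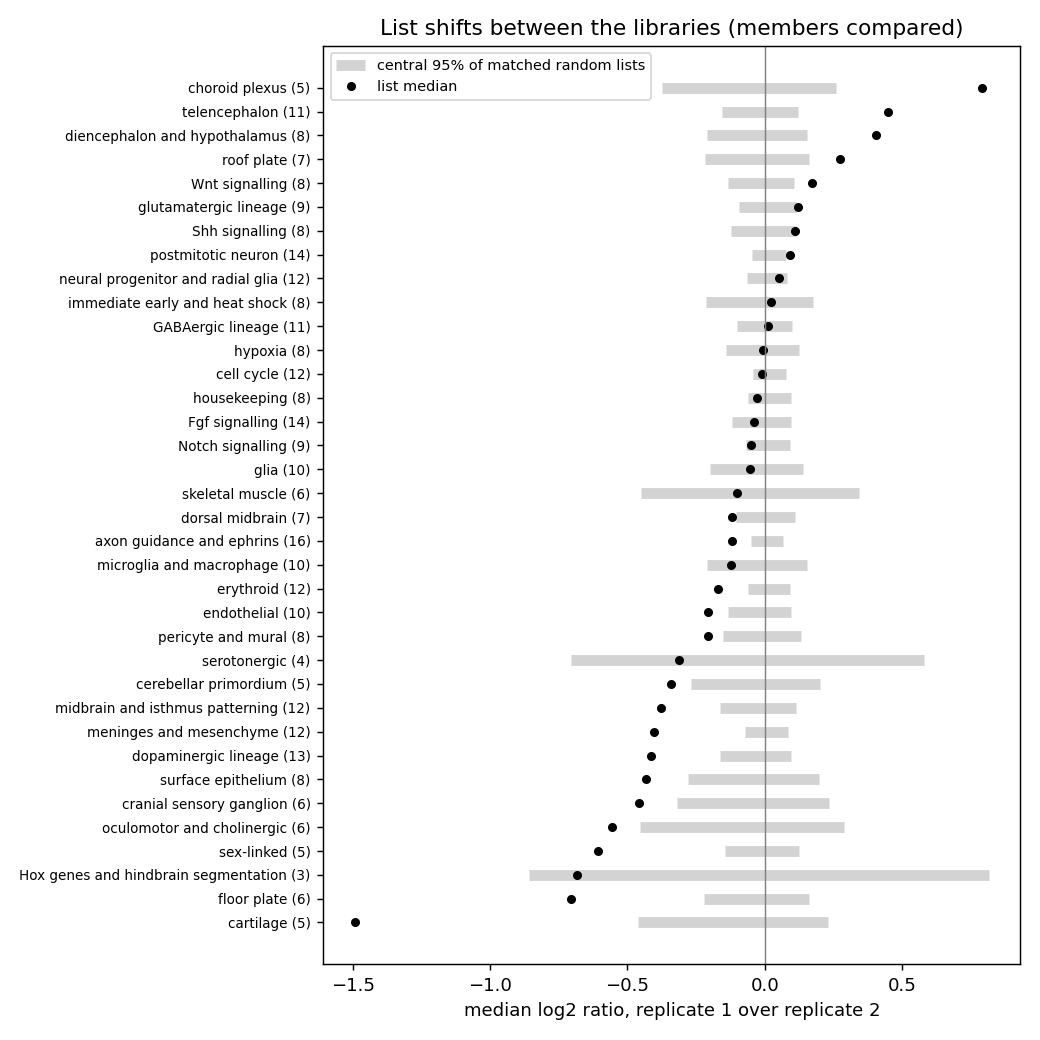
Median log2 ratio of replicate 1 over replicate 2 for each list (black points; members compared in parentheses) with the central 95% of matched random lists (grey bars), scaled by TMM. Choroid plexus (0.79) and telencephalon (0.45) lie furthest right and cartilage (-1.49) furthest left; under spike-in scaling all points move left and the Wnt, glutamatergic, Shh and neuronal medians become negative.

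**Figure D3:**
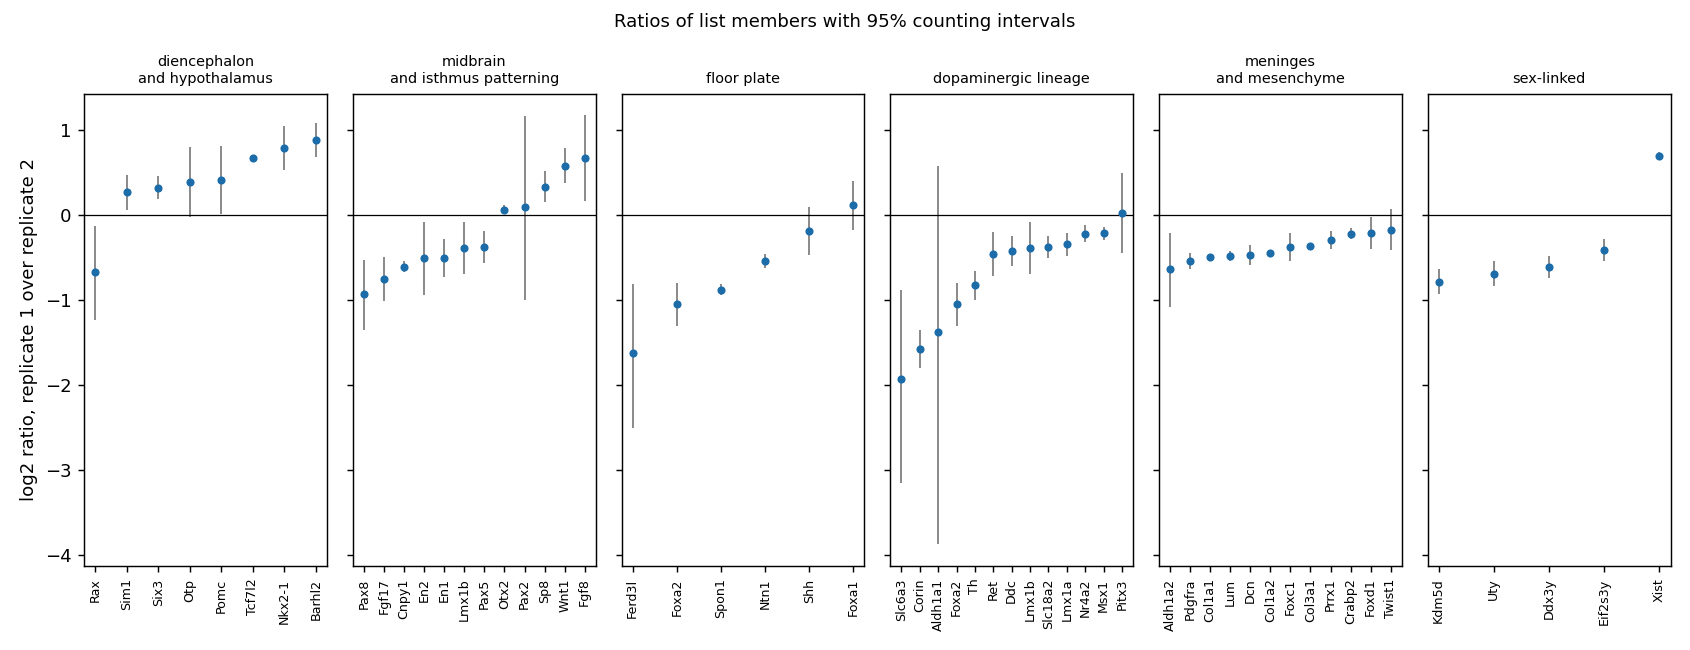
Log2 ratio of replicate 1 over replicate 2 for members of 6 lists (points) with 95% counting intervals (lines). All mesenchymal points lie below 0, and Xist (0.70) lies above the 4 Y-linked genes.

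Transcript structure was compared in 26 genes of neural splicing and patterning. Map2, a dendritic microtubule protein gene, was led by Map2-201 at 44.2% ± 1.43 of its TPM, with a coding length of 1401 nt, that of the short juvenile form. App was led by App-201 at 77.6% ± 4.31, coding length 2085 nt, the form without the Kunitz inhibitor domain. The neuronal splicing factor Srrm4 had the most dominant transcript, at 84.6% ± 0.310, and Cdc42 (80.8% ± 1.48) and Snap25 (80.8% ± 0.958) were also led by a single transcript, while Ank3 had the least dominant one, at 19.6% ± 1.06. For Pax6, shares were taken over the TPM of its protein-coding transcripts only. Those with a coding length of 1266 nt took 65.4% ± 4.08, those of 1308 nt 18.1% ± 0.987 and those of 53 nt 10.7% ± 2.87. In 12 of the 26 genes the leading transcript took at least 50% in both libraries. In 22 the same transcript led in both; Ptbp1, Clta, Fgfr2 and Pax6 differed. Among 10091 genes at 5 TPM or more with several annotated transcripts, the leading transcript differed between the libraries in 704 (6.98%), and its median share was 66.0%. Shares from short reads are model estimates whose error is not included in these SDs.

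Synthetic ERCC RNAs, added as a reference, took 4.02% of counts in replicate 1 (Wilson 95% interval 4.01 to 4.03) and 3.38% in replicate 2 (3.38 to 3.39), a mean of 3.70% ± 0.453. At least 3 counts were found for 76 and 79 of the 96 spike-ins, 73 of them in both libraries and 14 in neither. The ratio of spike-in totals was 0.937, against 0.783 for gene counts. Over 24 spike-ins with at least 2000 counts, the median log2 ratio of raw counts was -0.06 (SD 0.07).

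Each library had been quantified against an older (M4) and a newer (M21) annotation. Actb showed what a change of gene model does: it stood at 10302 ± 659 TPM with M21 and 4968 ± 246 with M4, although mean counts were 181618 and 181626, because its effective length was 834 nt against 1815. Nrcam, a neural adhesion gene, was 2.20-fold higher with M21 and the transcription factor gene Foxd1 2.02-fold higher with M4. Of 14936 genes compared, 548 (3.67%) differed at least 2-fold, 350 higher with M21 and 198 with M4. Pearson's r across genes was 0.971 and Spearman's rho 0.982, genes not being independent replicates. The largest differences lay in genes with few or no counts under one of the annotations. Gm6565 stood at 0 TPM with M21 and 99.01 with M4, and Gm6361 at 96.2 and 0. Gm10774 (55.5) and Gm5537 (15.6) had counts with M21 only. Gm49342 (40.7), RF01953 (15.9) and Gm10197 (15.8) had them with M4 only. Nupl1 stood at 0.01 with M21 and 44.5 with M4, Gm7292 at 0.225 and 112, and Gm6741 at 0.05 and 30.2. Gm6565, Gm6361, Gm10774, Gm6741 and Gm5537 are processed pseudogenes, and reads shared with similar copies make their values uncertain.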

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

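The test of counting noise, the choice of the 12 regional and mesenchymal lists whose GC and length trends were removed, and the patterns weighed here were chosen only after the list values were seen; the separate gene lists were written after those values too, but before the values of their own members were looked at. Some data entered no comparison. Rows with numeric identifiers of transfer RNA length held 18 counts in replicate 1 and 29 in replicate 2, sums spread over 6 and 9 of 26248 rows that show no signal in any one of them. Of 884 gene identifiers found with the M4 annotation alone, 169 had over 3 counts in both libraries, and 106 reached 1 TPM; together the 884 took 0.306% of M4 gene counts in replicate 1 and 0.295% in replicate 2.

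Regional and mesenchymal genes differed between the pools. Counting noise alone is argued against, since 80.5% of 41 genes in the separate lists (exact 95% interval 65.1 to 91.2) went the way predicted for their list where noise gives 50%, and so is GC and length bias, since removing those trends left 102% of the mean shift of 12 lists. A candidate explanation is that the pools held different amounts of neighbouring forebrain and of head mesenchyme: a separate list of rostral genes had a median log2 ratio of 0.27 (percentile 100) and a separate list of mesenchymal genes -0.42 (percentile 0). A different share of ventral midbrain stays open, since its separate list reached -0.16 (percentile 3.77), between the bounds set for either reading. Beyond these shares no biological explanation was tested, since the design has 1 group, and a difference in embryo stage stays open.

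Xist and the Y-linked genes moved in opposite directions. GC and length bias is argued against, since 99.02% of the gap was left after those trends were removed. Pools of mixed sex may have differed in their ratio of male to female embryos: 4 X-linked genes known to escape inactivation had a median log2 ratio 0.10 above that of 453 other X-linked genes, with 3 of the 4 above it beyond counting error. Under a model in which Xist comes from female and the Y-linked genes from male embryos alone, ratios of 1.63 for Xist and 0.638 for the Y-linked genes correspond to 59.4% female in replicate 1 and 36.5% in replicate 2, a hypothesis that the labels cannot check. Beyond the sex ratio no biological explanation was tested.

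Genes differed in level between the annotations. Among the 548 genes with a 2-fold difference, 56.8% had expected counts that themselves differed by 1.5-fold or more, in line with reads being assigned to other genes. Counts stayed within 1.2-fold for 29.9%, a share between the bounds set for either reading. A change of effective length alone was thus left undecided for the 548 genes as a set. For those 29.9%, Actb among them, TPM divides near-equal counts by effective length, so the gap comes mostly from length. No biological explanation applies to tables made from the same reads.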

How the results depend on the processing

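Each alternative here was set before the data were examined. Genes detected ran from 11362 at a limit of 5 TPM to 17674 at 0.5, lists with most members detected from 21 to 33, and shifted lists from 20 to 23, while the progenitor to neuron difference and the spike-in share held under every alternative run. The midbrain to telencephalon difference was -1.05 with a pseudocount of 1. The midbrain to Hox difference was 4.92 with FPKM, 2.65 with a pseudocount of 1 and 7.80 with 0.01, since most Hox values are near 0, and it turned to -0.12 with detected members only, because that left the Hox list nearly empty. A share of 80% left 3 genes with a dominant transcript. Differences between annotations numbered 358 in counts scaled to a fixed total, which removes the length term, and 1101 at 1.5-fold. Replicate differences numbered 208 at 50 counts or more (1.37% of genes against 4.23%; the cause was not tested) and 1429 at 1.5-fold. The cerebellar shift became 0.029 at 50 counts, where Ptf1a left the list. Using either replicate alone, genes detected ranged from 16208 to 16430, lists from 31 to 32, the telencephalon difference from -1.25 to -1.09, the Hox difference from 5.29 to 5.71, the progenitor difference from -1.69 to -1.47, dominant transcripts from 13 to 14, the spike-in share from 3.38% to 4.02% and annotation differences from 596 to 602. A limit of 5 TPM moved the number of members detected in 16 lists, one of 0.5 raised muscle genes from 2 to 6 of 8, FPKM lowered choroid plexus genes from 5 to 3, and replicate 2 alone raised cerebellar genes from 3 to 5; the cause was not tested. At 50 counts 2 lists had no value. No paired analysis was possible because the series has 1 group. Depth limits statements on genes below about 10 counts.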

Other observations

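The genes in this part were looked up after the level of Afp was seen, and 18 were looked up. They encode proteins of the yolk sac, liver and plasma. Of these, 12 had at least 10 counts in a library and were higher in replicate 1 beyond counting error, a tally that includes Afp itself; Afp, Apoa4, Spp2, Fgg, Amn and Apob reached 10 counts in replicate 1 only. Afp had 420 counts against 4, the apolipoprotein genes Apoa1 89 against 23, Apoa2 37 against 19 and Apob 31 against 5, and the retinol carrier gene Rbp4 55 against 26. Apoa4 and Spp2 each had 23 against 0. The receptor gene Cubn had a log2 ratio of 1.09 and the transferrin gene Trf 0.31. Alb, the albumin gene, had 0 counts in both libraries. Ttr, placed with the choroid plexus genes, is also made in yolk sac and liver, and had 768 counts against 346.

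Outside the lists, other coding genes at 5 TPM or more with large ratios were chosen after their values were seen. Gm4724 (223 counts against 98, log2 ratio 1.55) and Gm49325 (114 against 59, 1.31) were higher in replicate 1, and Gm4724 lies among the similar zinc-finger genes of chromosome 2. Higher in replicate 2 were Rtl3 (162 against 609, -1.55), derived from a retrotransposon, the neuropeptide gene Calca (150 counts against 563, log2 ratio -1.54), the opioid precursor gene Penk (631 against 2061, -1.34), the craniofacial homeobox gene Alx1 (135 against 498, -1.52), the mesenchymal gene Foxc2 (253 against 844, -1.37), the cartilage genes Cnmd (144 against 458, -1.31) and Mia (32 against 101, -1.29), and the interferon-induced gene Ifi27 (52 against 156, -1.22).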
